A study of Mus musculus with 7 samples.

How the data were processed

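Gene counts were taken from 1 table with 7 libraries of isolated mouse pancreatic islets, 4 of control and 3 of Traf6 KO mice. Per the labels' protocols, mice received a 60% high-fat diet for 15 weeks, islets recovered in medium for 24 hours after isolation, and libraries were read in paired 151 bp cycles on a NovaSeq. The labels name a tissue DNA kit for the RNA extraction. The labels do not name the driver of the knockout, the age, the sex or the litter of the mice. Each library carries its own animal tag and was taken as 1 mouse; if some shared an animal, the p-values would measure only the spread between these samples.

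The authors deposited whole-number counts per gene (100% of values are whole), not normalized, with 1 column per library. STAR 2.6.1b, RSEM 1.3.1, FastQC and the build GRCm38 are named in the submitters' processing notes, with no role or order, so the counts may be rounded RSEM estimates, in which reads shared between similar genes are divided by a model. The annotation, the strand setting and any filter on genes are not given in the sources used here. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart. Of 55487 gene identifiers in the table, 55227 matched GENCODE release M21 on GRCm38, 52927 of them with the same symbol, and coordinates were taken from that annotation. A total of 26497 genes had 0 counts in all libraries.

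Groups were taken from the genotype in the labels, and each column from the library description. Totals ran from 22104256 to 29917292 counts. Shares of counts have exact (Clopper-Pearson) 95% binomial intervals, and single counts exact Poisson intervals, which cover counting error only. No pair of libraries agreed within sampling noise over genes with at least 20 counts in the pair (lowest chi-square per gene 21.82 over 21 pairs), so each library was counted as 1 replicate.

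Counts were analysed in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood fit and F test, TMM normalization, genotype as the only term, filterByExpr by group with a minimum count of 10 and a minimum total of 15), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. CPM stands throughout for the count divided by the product of library total and TMM factor, on the usual CPM scale. TMM factors were 0.954, 1.305, 1.256 and 1.279 in the libraries labelled control 1 to 4 and 0.5, 0.74 and 1.353 in Traf6 KO 1 to 3, so a CPM of an acinar-rich library is raised against one computed on its plain total. Fold changes are Traf6 KO over control, and their SE was derived from the fold change and the F statistic. Values of named genes after ± are SE for log2 fold changes and SD for CPM and list means.

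Gene lists were fixed before the data were examined, as were the tests, the rule for named genes and the alternative settings below. The 31 lists hold markers of islet alpha cells, delta and gamma cells, acinar, ductal, endothelial, stellate and fibroblast, macrophage and myeloid, lymphocyte, Schwann and neural cells and adipocytes, and genes of beta-cell identity, insulin exocytosis, beta-cell disallowed and dedifferentiation genes, Toll-like and interleukin-1 receptor signalling, NF-kB targets, the interferon response, mitophagy, autophagy and lysosomes, mitochondrial dynamics, mitochondrially encoded genes, nuclear oxidative phosphorylation, the unfolded protein response, antioxidants, the cell cycle, apoptosis and p53, fatty acid and lipid handling, cholesterol synthesis, glycolysis and hypoxia, immediate-early and heat-shock genes, ribosomal proteins, and X-inactivation with Y-linked genes. Some genes stand in more than 1 list. Lists with at least 5 tested genes, without the sex list, made 29 tests by limma 3.58.1 camera on voom values with a preset inter-gene correlation of 0.01, two-sided, and again with an estimated correlation and with fry. Cell-type list means are the mean log2(CPM + 1) per library. Exact two-sided permutation tests over the 35 splits of 7 libraries into 4 and 3 used scipy 1.17.1, and their smallest p is 0.0571.

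The genes named are Traf6; among genes that pass, those with a mean CPM of at least 1 in the higher group, no overlap between groups and a symbol that is not predicted, clone-based or a pseudogene, up to 12 in each direction by fold change, and where fewer than 5 pass, the 5 of that direction with the smallest p that meet the other criteria, stated not to pass; in each list up to 4 members with the smallest p; and 32 genes of islet function, mitophagy, innate signalling and stress named whatever their values, of which 2 are left out under a restriction on naming, not because of their values or a filter. Genes named outside this rule are said to have been chosen after their values were seen.

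Besides these settings, results were recomputed with DESeq2 size factors, upper-quartile factors, the DESeq2 1.42.0 Wald test, limma-voom without and with sample quality weights, no low-count filter, a mean CPM of at least 1, the replicate number as a block, the animal tag series as a term, Q- and R-tagged animals alone, the acinar or the myeloid list mean as a covariate, and each library left out in turn. The edgeR and camera steps were tested on simulated data with 200 changed genes and a shifted list of 40 genes among 16203. The data were drawn from the means and library sizes of the Traf6 KO and control libraries. Changed genes were taken only from those above a floor of mean counts, so the rates do not cover genes with low counts. Over 5 simulations edgeR called 35.2% of genes changed 2-fold, 78.0% at 4-fold, 92.0% at 8-fold, 97.2% at 16-fold and 0.06% of unchanged genes. At an unadjusted p under 0.05 camera called the list of 40 genes shifted by 1 log2 unit in 5 of 5 simulations and an unshifted list in 0 of 5. The simulated genes were drawn independently of each other. These rates therefore do not cover lists whose genes move together, such as acinar markers (estimated correlation 0.943). For the genes called without Traf6 KO 3, 10 further simulations kept control 1 and Traf6 KO 3 at the control mean and shifted Traf6 KO 1 and 2 by the fitted fold changes, of every gene or of the called genes alone (442 to 1610 genes called). Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.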

Results

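RNA was sequenced from isolated pancreatic islets of mice fed a 60% high-fat diet for 15 weeks. The islets came from 4 control mice and from 3 Traf6 KO mice, in which Traf6, the gene of an E3 ubiquitin ligase that acts below Toll-like and interleukin-1 receptors, was targeted. Each library was one sample of the deposited gene count table. The series title places the work in glucose homeostasis, innate immune signals and mitophagy, the selective removal of mitochondria by autophagy. The comparison of both genotypes therefore asked which islet transcripts differed when Traf6 was targeted under a high-fat diet. Library totals were 29917292, 27497398, 27213834 and 22161097 counts in the libraries labelled control 1 to 4 and 22104256, 25091055 and 22847713 counts in Traf6 KO 1 to 3.

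The targeted gene, Traf6 (ENSMUSG00000027164, chromosome 2, 101678429 to 101701669 on GRCm38), is protein-coding. Its level was 17.9, 25.5 and 22.1 CPM in controls 1 to 3 and 12.7 CPM in the library labelled control 4. It was 14.8, 15.4 and 14.5 CPM in Traf6 KO 1 to 3. The mean was 19.6 ± 5.56 CPM in control (SD, n = 4) and 14.9 ± 0.447 CPM in Traf6 KO (SD, n = 3), and the log2 fold change was -0.40 ± 0.22 (SE, edgeR adjusted p = 0.416). An exact two-sided permutation test of log2 CPM gave p = 0.2286, where 0.0571 is the smallest p that 4 against 3 libraries allow. The library labelled control 4 had the lowest Traf6 level of the 7, below each Traf6 KO library, so its label is not borne out by this gene, and every direction below was drawn with it among the controls. Without it the log2 fold change was -0.55 (edgeR adjusted p = 0.339). The deposited value counts the whole gene, so a deleted exon is not seen apart from the rest, and islets also hold cells other than beta cells. Animal tags in the sample names set the library labelled control 4 and Traf6 KO 3 (tag S) apart from the others (tags Q and R). Among the Q- and R-tagged libraries alone the log2 fold change was -0.54 (edgeR adjusted p = 0.157), and tag S holds 1 library of each genotype, which allows no test. The Traf6 KO libraries tagged Q, Traf6 KO 1 and 2, are those rich in acinar transcripts, as given below. With the acinar list mean as a covariate the log2 fold change of Traf6 was -0.25 ± 0.26 (SE).

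The libraries differed widely in exocrine pancreas transcripts. The 29 acinar marker genes, which encode digestive enzymes and their regulators, took 20.3% of all counts in control 1, 0.49% in control 2, 0.467% in control 3 and 3.24% in the library labelled control 4. They took 56.4% in Traf6 KO 1, 43.1% in Traf6 KO 2 and 1.64% in Traf6 KO 3. The exact 95% binomial interval of each share was at most 0.041 percentage points wide, which covers counting error only. The mean log2(CPM + 1) of the list was 7.40 ± 2.57 in control (SD, n = 4) and 10.8 ± 3.35 in Traf6 KO (SD, n = 3), a difference of 3.36 with p = 0.1714 in an exact two-sided permutation test (0.653 after Benjamini-Hochberg adjustment over the 10 cell-type lists). The difference was 5.27 without Traf6 KO 3 and 2.17 without Traf6 KO 1. Prss2, a trypsinogen, had a log2 fold change of 3.21 ± 1.71, Bhlha15, a transcription factor of secretory cells, one of 1.78 ± 0.61 and Reg2 one of 2.71 ± 1.13 (SE, edgeR adjusted p = 0.388, 0.242 and 0.301). Without Traf6 KO 1 the values of Prss2 and Reg2 were 2.35 and 1.49, and without control 1 they were 5.82 and 3.43. The levels of single trypsinogen, amylase and elastase genes are uncertain, since reads can be shared between these near-identical copies.

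**Figure D1:**
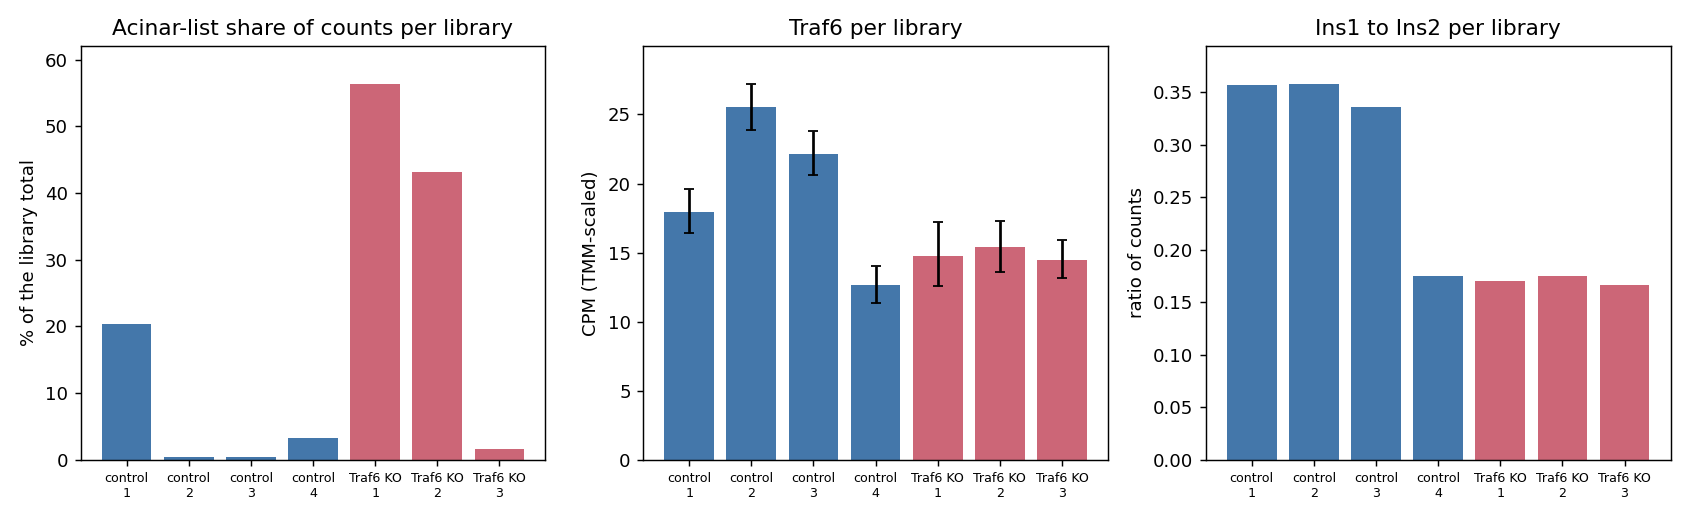
Bars show, for each of the 7 libraries (blue, control; red, Traf6 KO), the share of counts in acinar list genes in percent, the Traf6 level in CPM with its exact 95% Poisson interval, and the ratio of Ins1 to Ins2 counts. Acinar shares of 43.1% and 56.4% mark Traf6 KO 2 and 1, and the library labelled control 4 lies at 12.7 CPM for Traf6 and 0.175 for the insulin ratio.

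Other cell-type lists moved less, and none passed the exact two-sided permutation test over the 35 splits of 4 and 3 libraries, which cannot go below 0.0571. Ductal markers averaged 3.98 ± 0.269 in control (SD, n = 4) and 4.50 ± 0.424 in Traf6 KO (SD, n = 3) on the log2(CPM + 1) scale (exact p = 0.1143), with 11 of 14 tested genes above 0, among them Krt19 at a log2 fold change of 2.25 ± 0.77 and Clu at 1.98 ± 0.61. Without Traf6 KO 1 these values were 1.351 and 1.2, and with the acinar level as a covariate 0.83 and 0.60. Clu was higher in acinar-rich libraries (1130, 530 and 167 CPM in Traf6 KO 1 to 3, 264 CPM in control 1). Stellate and fibroblast markers averaged 2.40 ± 0.336 and 2.98 ± 0.762 (exact p = 0.2286, n = 4 and 3). Among them Pdgfra, a growth factor receptor of mesenchymal cells, passed when adjusted over the list alone (0.211 ± 0.146 CPM in control and 1.68 ± 0.801 CPM in Traf6 KO, SD, n = 4 and 3; adjusted p = 0.0234 by edgeR), while Fn1 (2.09 ± 0.74) and Dcn (1.72 ± 0.66) did not, and stood at 1.045 and 1.137 without Traf6 KO 3. Macrophage and myeloid markers averaged 3.91 ± 0.694 and 3.67 ± 0.385 (exact p = 0.8571, n = 4 and 3), and the library labelled control 4 stood at 4.94 against 3.46, 3.61 and 3.62 in controls 1 to 3. Tyrobp, C1qb and Adgre1 of this list had log2 fold changes of -1.10 ± 0.58, -0.86 ± 0.50 and -0.60 ± 0.56, and of -0.28, -0.19 and 0.08 without that library. Lymphocyte markers averaged 1.5 ± 0.828 and 2.10 ± 0.685 (exact p = 0.3429, n = 4 and 3), with Ighm at 3.44 ± 1.29 and Ms4a1 at 2.08 ± 1.27. Traf6 KO 3 carried the value of Ighm, with 401 CPM against 28.3 and 12.3 CPM in Traf6 KO 1 and 2, and without it the log2 fold change was 0.567. Without control 3 that of Ms4a1 was 3.18. Endothelial markers averaged 4.37 ± 0.243 and 4.22 ± 0.142 (exact p = 0.4571, n = 4 and 3), with Eng at -0.41 ± 0.14 and Esam at -0.39 ± 0.14. Schwann and neural markers averaged 1.92 in both groups (exact p = 0.9714, n = 4 and 3), with Mbp at 0.40 ± 0.15. Adipocyte markers averaged 1.04 ± 0.057 and 1.08 ± 0.054 (exact p = 0.4, n = 4 and 3), and too few of them were tested for a list test. In limma camera with the preset correlation, acinar (adjusted p = 6.55e-08), stellate and fibroblast (0.00451) and lymphocyte (0.00704) markers were called in the upward direction and endothelial markers (0.0387) in the downward direction, while ductal (0.147), myeloid (0.278) and Schwann (0.738) markers were not called. The acinar, stellate, lymphocyte and endothelial calls were lost with an estimated correlation (adjusted p = 0.935 for each). Camera called ductal markers upward without Traf6 KO 3 (adjusted p = 0.0338) and Schwann markers upward with the acinar covariate (0.0158). It called myeloid markers downward without control 1 (0.0459), with the tag series as a term (0.000325) and with no low-count filter (0.0495). The replicate block also called ductal markers (0.00999). The stellate and endothelial calls were also lost with the acinar covariate (adjusted p = 0.143 for each). The stellate call was lost without Traf6 KO 1 (adjusted p = 0.131) or Traf6 KO 3 (0.202), the lymphocyte call without control 1 (0.180), control 2 (0.109), Traf6 KO 1 (0.0604) or Traf6 KO 3 (0.404), and the endothelial call without the library labelled control 4 (0.375), Traf6 KO 1 (0.162) or Traf6 KO 2 (0.0766). It was also lost with upper-quartile factors (0.0541), a mean CPM of at least 1 (0.0521), quality weights (0.0827) and the myeloid covariate (0.1445), and quality weights ended the stellate (0.5985) and lymphocyte (0.672) calls. The tag series as a term also ended the lymphocyte call (camera adjusted p = 0.0587). In 1 of 20 camera alternatives at the preset correlation the stellate list pointed downward. Among Q- and R-tagged animals the stellate (0.250), lymphocyte (0.0539) and endothelial (0.106) lists were not called.

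No single gene passed the test between genotypes. Of 16203 genes tested with edgeR, 0 had an adjusted p under 0.05, the smallest adjusted p was 0.176, and 2589 genes (16%) had an unadjusted p under 0.05. In 904 genes every Traf6 KO library lay above every control, and in 1406 genes below, together 14.26% of the genes. Chance gives 5.71% on average over all splits of the libraries. Genes that move together can set any given split far from that average. The share was not computed for the other splits, so an excess over chance was not tested. Other tools gave other counts: limma-voom called 0 genes, the DESeq2 Wald test called 438 higher and 196 lower genes, and limma-voom with sample quality weights called 669 higher and 377 lower genes. Leaving out Traf6 KO 3, which leaves as Traf6 KO both libraries with acinar shares of 43.1% and 56.4%, edgeR called 568 genes higher and 133 lower. By its Xist and Y-linked counts, given below, Traf6 KO 3 is also the only library from a female, so sex differs in that comparison too.

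The genes with the smallest p did not pass after adjustment (edgeR adjusted p = 0.1765 for each). The 5 with higher values in every Traf6 KO library were Amotl2, a regulator of Hippo signalling, with a log2 fold change of 1.07 ± 0.14 (SE; 14.3 ± 0.888 CPM in control, n = 4, and 29.9 ± 5.67 CPM in Traf6 KO, n = 3), Plk2, a stress-responsive kinase, at 1.83 ± 0.24, the membrane-remodelling gene Snx18 at 0.73 ± 0.096, the imprinted zinc-finger gene Plagl1 at 1.28 ± 0.17 and the mRNA-decay factor Zfp36l1 at 1.57 ± 0.23. The 5 with lower values in every Traf6 KO library were the aldo-keto reductase gene Akr1c13 at -0.64 ± 0.087, Spa17 at -0.89 ± 0.12, the proteasome activator gene Psme2 at -0.60 ± 0.087, Fam183b at -0.62 ± 0.093 and Uqcc2, an assembly factor of respiratory complex III, at -0.61 ± 0.096. All 10 kept their direction in every alternative. They were chosen for having no overlap between groups, so leaving out a library could not turn their direction, and this stability is no separate support.

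Beta-cell genes lay lower in Traf6 KO. Ins1, an insulin gene, stood at 35764 ± 10440 CPM in control (SD, n = 4) and 12829 ± 1946 CPM in Traf6 KO (SD, n = 3), a log2 fold change of -1.48 ± 0.49 (SE, edgeR adjusted p = 0.235). Its level was 44548, 36488 and 41107 CPM in controls 1 to 3 and 20911 CPM in the library labelled control 4. An insert in 1 copy of Ins1, a candidate raised below, could also lower it, so Ins1 alone does not show a loss of beta-cell expression. Ins2, the second insulin gene, had a log2 fold change of -0.64 ± 0.62 (edgeR adjusted p = 0.637), and of -0.79 ± 0.19 (SE) with the acinar level as a covariate. It stood at 117150 ± 10390 CPM in control (SD, n = 4) and 75233 ± 10860 CPM in Traf6 KO (SD, n = 3). Every Traf6 KO library lay below every control (p = 0.0571 in an exact two-sided permutation test, the smallest possible). Of the 31 genes of beta-cell identity and function, 26 had a log2 fold change below 0 with a median of -0.22, 9 had every Traf6 KO library below every control, and 0 passed over all genes tested or adjusted over the list alone. Among them were Ucn3, a marker of mature beta cells, at -0.46 ± 0.15, Kcnj11, a subunit of the potassium channel that gates insulin release, at -0.38 ± 0.11, the transcription factor genes Pdx1 at -0.21 ± 0.15 and Mafa at -0.37 ± 0.43, and the glucose transporter gene Slc2a2 at -0.04 ± 0.15. Without Traf6 KO 3 the values of Pdx1 and Mafa were -0.396 and -0.98 and the list's median was -0.38, and without Traf6 KO 1 both genes were near 0 (-0.071 and -0.06). The list was called in the downward direction by camera (adjusted p = 1.33e-05) and not with an estimated correlation (adjusted p = 0.897). The list's mean log2(CPM + 1) was 9.24 ± 0.036 in control (SD, n = 4), and in Traf6 KO it was 8.75 and 8.96 in the acinar-rich libraries 1 and 2 and 9.16 in library 3. With the acinar level as a covariate camera still called the list downward (adjusted p = 0.0111), with a median of -0.17. Without the 3 acinar-rich libraries (control 1, Traf6 KO 1 and Traf6 KO 2), a choice made after the data were seen that leaves 1 Traf6 KO library, it did not (adjusted p = 0.373).

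The ratio of Ins1 to Ins2 within a library does not depend on scaling. It was 0.357, 0.358 and 0.336 in controls 1 to 3, 0.175 in the library labelled control 4, and 0.17, 0.175 and 0.166 in Traf6 KO 1 to 3. The mean log2 ratio was -1.76 ± 0.50 in control (SD, n = 4) and -2.55 ± 0.035 in Traf6 KO (SD, n = 3), with p = 0.0571 in an exact two-sided permutation test, the smallest that this design allows. Among the Q- and R-tagged libraries the ratio was 0.336 to 0.358 in control and 0.17 to 0.175 in Traf6 KO, and in the S-tagged pair it was 0.175 in the library labelled control 4 and 0.166 in Traf6 KO 3. The 2 insulin genes are similar in sequence, so the split of reads between them is an estimate.

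Genes whose expression is normally low in beta cells, or that mark their dedifferentiation, lay higher in Traf6 KO. Of 18 tested, 15 had a log2 fold change above 0 (median 0.95), 0 passed over all genes tested and 9 passed when adjusted over the list alone, each in the upward direction. Among these 9 were Zfp36l1, the hexokinase gene Hk2 at 2.51 ± 0.48, Smad3, a transducer of TGF-beta signals, at 1.68 ± 0.33, Pdgfra at 2.97 ± 0.60 and the lactate dehydrogenase gene Ldha at 1.12 ± 0.38 (SE). Camera called the list (adjusted p = 1.33e-05), and not with an estimated correlation (adjusted p = 0.897). The mean log2(CPM + 1) of the list was 2.19, 1.91, 1.92 and 2.30 in the libraries labelled control 1 to 4 and 3.16, 2.56 and 2.62 in Traf6 KO 1 to 3, where the highest value stood in the library with the largest acinar share. Pdgfra is also in the stellate and fibroblast list, which camera called upward and whose mean was 3.63, 2.14 and 3.16 in Traf6 KO 1 to 3 and 2.40 ± 0.336 in control (SD, n = 4). Sox9, named here after its values were seen, is also in the ductal list. The change is thus not shown to lie in beta cells. With the acinar covariate Hk2 was at 1.70, Smad3 at 1.09 and Ldha at 0.55 ± 0.365, Ldha stood at 0.658 without Traf6 KO 1, and the list's median was 0.54. Insulin granule exocytosis genes had a median of -0.10, with 16 of 21 below 0 (camera adjusted p = 0.125; Syt5 at -0.42 ± 0.17, Cplx2 at -0.32 ± 0.15). The list was called downward without Traf6 KO 3 (adjusted p = 0.000621, median -0.28) and among Q- and R-tagged animals (0.000835), with quality weights (0.04695), no low-count filter (0.0147) and the replicate block (0.0363). It turned upward in 3 of 20 alternatives, among them, not called, without Traf6 KO 1 (0.966) and with the acinar covariate (0.870). Other islet endocrine lists were not called by camera in all libraries, and alpha-cell markers were called downward in 1 alternative, the acinar covariate with Traf6 KO 3 left out (adjusted p = 0.00745), chosen after the data were seen. Alpha-cell markers (adjusted p = 0.732, 4 of 11 above 0) had a median of -0.02 and a mean of 0.14, with the glucagon gene Gcg at -0.11 ± 0.45 and the amino acid transporter gene Slc38a5 at 1.94 ± 0.64. Slc38a5 was higher in acinar-rich libraries (133, 80.5 and 27.1 CPM in Traf6 KO 1 to 3, 41.8 CPM in control 1). Its log2 fold change was 0.75 with the acinar covariate and 2.56 without control 1. Delta- and gamma-cell markers (adjusted p = 0.736, 6 of 10 above 0) included the somatostatin gene Sst at -0.36 ± 0.29, Ppy at -0.26 ± 0.27, Rbp4 at -0.41 ± 0.19 and Spock3 at 0.67 ± 0.27.

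Mitophagy genes showed small differences in both directions. Of 42 tested, 24 lay above 0 and 18 below with a median of 0.05, 0 passed over all genes tested or adjusted over the list alone, and camera did not call the list (adjusted p = 0.407). Pink1, which encodes a kinase that marks damaged mitochondria, had a log2 fold change of 0.16 ± 0.22 (SE). The mitophagy receptor genes Bnip3 (-0.07 ± 0.13), Bnip3l (-0.01 ± 0.11) and Fundc1 (0.09 ± 0.12), the adaptor genes Sqstm1 (0.09 ± 0.15) and Optn (-0.14 ± 0.16), and Clec16a (0.06 ± 0.14) and Rnf41 (-0.16 ± 0.10), which encode parts of a ubiquitin ligase complex with Usp8, each had an edgeR adjusted p of 0.452 or more. The members with the smallest p were Nipsnap1 (-0.31 ± 0.11), Tbc1d15 (0.34 ± 0.12), Usp8 (0.29 ± 0.10) and the autophagy kinase gene Ulk1 (0.29 ± 0.11). In the simulated data the same test called 35.2% of genes changed 2-fold, so differences of this size were below what it could detect in most genes.

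**Figure D2:**
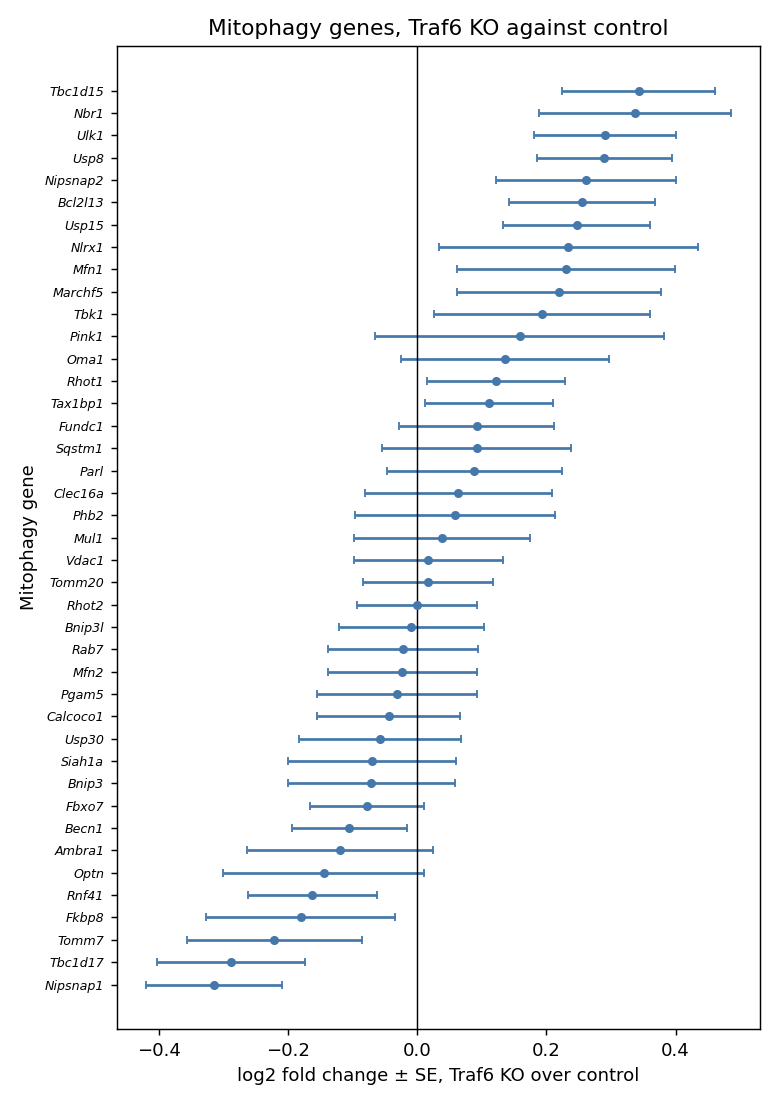
Each point is the log2 fold change of 1 mitophagy gene, Traf6 KO over control, for 41 of the 42 genes tested, with its SE as a horizontal bar; 1 gene is left out under a restriction on naming, not because of its value. Values of the 41 run from -0.31 (Nipsnap1) to 0.34 (Tbc1d15), and none passed the edgeR test.

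Other mitochondrial and lysosomal lists were mixed. Nuclear genes of oxidative phosphorylation had a median of -0.11 with 57 of 77 below 0, among them Ndufs5 at -0.37 ± 0.11 and Ndufc1 at -0.53 ± 0.16. Camera called the list in the downward direction (adjusted p = 1.33e-05) and not with an estimated correlation (adjusted p = 0.935), nor without Traf6 KO 3 (adjusted p = 0.796, median 0.003) or among Q- and R-tagged animals (0.417). Its mean log2(CPM + 1) was 5.90, 5.51 and 5.24 in Traf6 KO 1 to 3 and 5.69 ± 0.083 in control (SD, n = 4). Mitochondrially encoded genes had a median of 0.22 (adjusted p = 0.414 by camera, mt-Nd6 at -0.36 ± 0.14), and were called upward without the library labelled control 4 (0.0104) and with the replicate block (0.0246). Genes of mitochondrial dynamics and biogenesis had a median of 0.06 and a mean of 0.05 beside a camera direction downward (adjusted p = 0.991), with Fis1 and Mief2, both recruiters of the fission machinery, at -0.44 ± 0.11 and -0.48 ± 0.13. Autophagy and lysosome genes had a median of -0.02 and a mean of 0.03 (adjusted p = 0.991 by camera), with Atg9a at 0.43 ± 0.10 and the lysosomal hexosaminidase gene Hexa at -0.35 ± 0.097. None of these genes passed adjusted over its list alone.

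Components of Toll-like and interleukin-1 receptor signalling, the pathway in which TRAF6 acts, had a median of 0.13 with 24 of 39 above 0 and 0 passing over all genes tested or adjusted over the list alone. Traf4, a relative of Traf6, had a log2 fold change of 0.91 ± 0.22 and the kinase gene Irak2 one of 0.52 ± 0.15. The adaptor gene Myd88 (-0.04 ± 0.13) and the receptor genes Tlr4 (-0.56 ± 0.71) and Il1r1 (-0.13 ± 0.29) each had an edgeR adjusted p of 0.452 or more. So did the cytokine gene Il1b (1.62 ± 0.99), which is in the list of NF-kB targets and not in that of the components. Camera called the list in the upward direction (adjusted p = 0.0137), and not with an estimated correlation (adjusted p = 0.935), without control 1 (0.0523), without Traf6 KO 3 (0.208), among Q- and R-tagged animals (0.0772), with the tag series as a term (0.124), with quality weights (0.103), with no low-count filter (0.154) or without the 3 acinar-rich libraries (0.0685). It was called in 12 of 20 alternatives at the preset correlation. Targets of the transcription factor NF-kB were not called (median 0.28, 20 of 28 above 0, camera adjusted p = 0.125), with Nfkbia at 0.24 ± 0.49, Tnfaip3 at 2.18 ± 0.95, Nfkb2 at 0.47 ± 0.19 and Nfkbib at 0.25 ± 0.11. Traf6 KO 3 set the direction of several of these: without it the log2 fold change was -0.745 for Nfkbia, -0.295 for Tnfaip3 and -1.49 for Il1b, and the median of the NF-kB targets was -0.36. Camera called these targets upward without Traf6 KO 1 (adjusted p = 0.0231), without Traf6 KO 2 (0.000133) and with the acinar covariate (5.58e-08). The same held with the myeloid covariate (0.0207) and the replicate block (0.00655). Tlr4 stood at 0.24 without the library labelled control 4. Interferon response genes had a median of -0.24 (-0.483 to -0.013 when each library was left out) with 28 of 36 below 0, among them Usp18 at -0.42 ± 0.12 and Ifit3 at -0.82 ± 0.35. Camera called the list in the downward direction (adjusted p = 0.0387), and not with an estimated correlation (adjusted p = 0.935), nor without control 2 (0.109), control 3 (0.197), the library labelled control 4 (0.172), Traf6 KO 1 (0.0805) or Traf6 KO 2 (0.778). Upper-quartile factors (0.0742), a mean CPM of at least 1 (0.0521) and the myeloid covariate (0.195) also ended the call, and the acinar covariate turned the direction upward (0.614, median 0.04).

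Genes of the unfolded protein response lay higher in Traf6 KO, with 25 of 31 above 0 and a median of 0.45. Herpud1, a gene of endoplasmic reticulum-associated degradation, stood at 266 ± 67.5 CPM in control (SD, n = 4) and 647 ± 135 CPM in Traf6 KO (SD, n = 3), a log2 fold change of 1.28 ± 0.23. It passed when adjusted over the list alone (edgeR, adjusted p = 0.0176), as did Chac1, a target of the stress factor ATF4, at 1.87 ± 0.42 (edgeR, adjusted p = 0.0324), and 0 passed over all genes tested. Chac1 was highest in the library with the largest acinar share (61.8, 21.7 and 16.9 CPM in Traf6 KO 1 to 3), and its log2 fold change was 1.095 without Traf6 KO 1 and 1.20 with the acinar covariate. Syvn1 (0.45 ± 0.12), Txnip (0.66 ± 0.27) and the stress-induced transcription factor gene Ddit3 (0.69 ± 0.59) did not pass. Without Traf6 KO 3 the value of Ddit3 was -0.58. Camera called the list (adjusted p = 1.62e-05), and not with an estimated correlation (adjusted p = 0.897). The list's mean log2(CPM + 1) was 6.65, 6.75, 6.76 and 6.28 in the libraries labelled control 1 to 4 and 7.28, 6.92 and 7.15 in Traf6 KO 1 to 3, so that it also lay higher in Traf6 KO 3, with its acinar share of 1.64%. That library stands apart in stress genes, however, with a summed level of immediate-early and heat-shock genes of 31758 CPM against 2651 to 10420 CPM in the others, and it held 12998 counts of Xist against 0 to 11 in the others. Its level therefore does not set a rise from Traf6 loss apart from a state of that library. In the list of apoptosis and p53 genes 17 of 23 lay above 0. The 3 that passed when adjusted over the list alone were Mcl1 (0.56 ± 0.12) and Bcl2 (0.90 ± 0.21), which restrain apoptosis, and the p53 target Trp53inp1 (1.11 ± 0.30), which was at 0.55 without Traf6 KO 3. Camera called this list upward (adjusted p = 0.0387), and not with an estimated correlation (adjusted p = 0.897), nor without control 2 (0.0964), Traf6 KO 1 (0.102) or Traf6 KO 3 (0.245), nor among Q- and R-tagged animals (0.171), with quality weights (0.307), no low-count filter (0.1505) or a mean CPM of at least 1 (0.0755). Antioxidant genes divided evenly, with 12 of 24 above 0, a median of -0.01 and a mean of 0.28 (camera downward, adjusted p = 0.975). In this list Gclc, a subunit gene of glutathione synthesis, stood at 0.66 ± 0.16 and the catalase gene Cat at 1.85 ± 0.51 (0.67 with the acinar covariate).

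Among metabolic genes, Scd1, a fatty acid desaturase, had a log2 fold change of 1.60 ± 0.25 and Ppara, a transcription factor of fatty acid oxidation, one of 2.80 ± 0.53. Both passed when adjusted over the list of fatty acid oxidation and lipid handling alone (edgeR, adjusted p = 0.00639 and 0.0113). Ppara was low in both groups (0.131 ± 0.0309 CPM in control, n = 4, and 0.978 ± 0.517 CPM in Traf6 KO, n = 3, SD). Its log2 fold change was 2.17 with the acinar covariate. The list was not called by camera (14 of 28 above 0, adjusted p = 0.496). In glycolysis and hypoxia, 4 of 22 genes passed when adjusted over the list alone, Hk2 and Pfkfb3 (0.67 ± 0.18) upward and Pfkl (-0.39 ± 0.086) and Eno1 (-0.32 ± 0.092) downward. The list's median was -0.09 and its mean 0.12 (camera downward, adjusted p = 0.491). Cholesterol synthesis genes were not called (median -0.11, camera adjusted p = 0.414), with Pmvk at -0.55 ± 0.15 and Sc5d at 0.41 ± 0.12. They were called downward without Traf6 KO 3 (0.00297, median -0.29), among Q- and R-tagged animals (0.0247), with the tag series as a term (0.0469) and with the acinar covariate and Traf6 KO 3 left out (9.54e-05). Cell-cycle genes lay above 0 in 30 of 32 cases (median 0.81), with Mki67 at 1.17 ± 0.64 (0.323 without Traf6 KO 1), Mcm2 at 0.52 ± 0.18 and Ccnd1 at -0.27 ± 0.11. Their median was 0.157 to 1.076 when each library was left out. Ribosomal protein genes lay above 0 in 55 of 59 cases (median 0.32, Rpl23 at 0.77 ± 0.39). Camera called cell-cycle genes (adjusted p = 0.0025) and ribosomal protein genes (adjusted p = 0.00704) in the upward direction, and neither with an estimated correlation (adjusted p = 0.935). With the acinar level as a covariate the cell-cycle genes were no longer called (adjusted p = 0.851, median 0.07) and the ribosomal protein genes were called downward (3.93e-07, median -0.28). The mean log2(CPM + 1) of the ribosomal list was 8.34, 7.65 and 6.87 in Traf6 KO 1 to 3. It was 7.67, 7.18, 7.34 and 7.42 in the libraries labelled control 1 to 4. Traf6 KO 1 thus lay above every control and only Traf6 KO 3 below every control. Leaving out the 3 acinar-rich libraries leaves Traf6 KO 3 as the only Traf6 KO library, so that setting shows 1 library and not the genotype. With no low-count filter the ribosomal list was not called (0.544). Without control 2 neither list was called (adjusted p = 0.109 and 0.0813), and without Traf6 KO 1 the cell-cycle list was not (0.181) and the ribosomal list was called downward (0.0326).

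**Figure D3:**
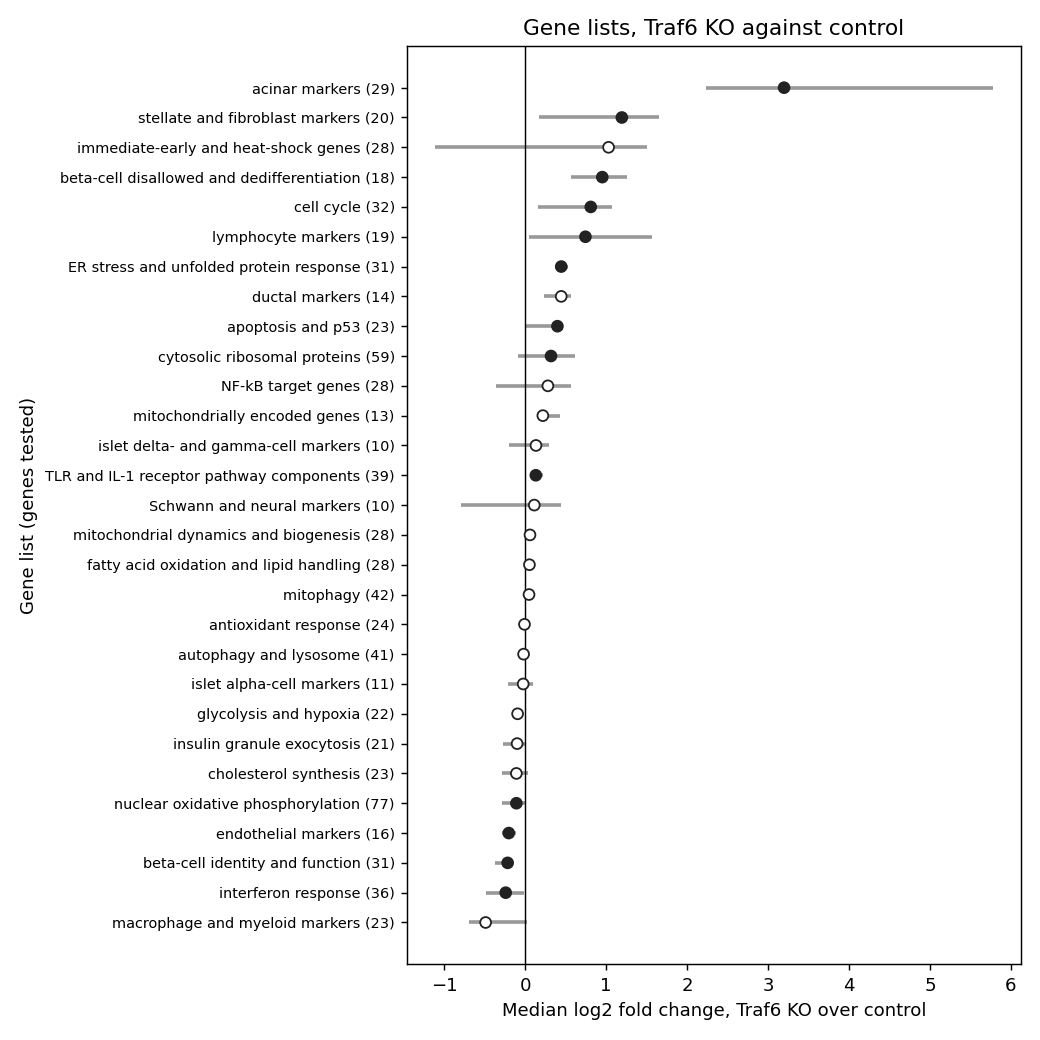
Each point is the median log2 fold change, Traf6 KO over control, of the tested genes of 1 of 29 lists, with the number of genes in parentheses; grey lines span the medians when each library in turn is left out, and filled points are lists with a camera adjusted p under 0.05 at the preset correlation. Medians run from -0.49 for myeloid markers to 3.20 for acinar markers.

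In all, camera with the preset correlation called 13 of 29 lists. With an estimated correlation it called 0, and fry, which tests whether a list's genes move on balance one way, called 0. Fry's test of change in either direction called 4 lists: the disallowed and dedifferentiation genes (adjusted p = 0.00694), apoptosis and p53 (0.00694), glycolysis and hypoxia (0.0138) and the Toll-like and interleukin-1 receptor components (0.042). Immediate-early and heat-shock genes were not called by camera in all libraries (median 1.03, 28 of 28 above 0, adjusted p = 0.28), with Egr2 at 3.43 ± 1.29 and Egr3 at 3.73 ± 1.34. Without Traf6 KO 3 their median was -1.11, camera called them downward (adjusted p = 9.68e-05), and Egr2 and Egr3 were at -0.14 and -0.17. Camera called this list upward without Traf6 KO 1 (adjusted p = 0.0358) or Traf6 KO 2 (0.00155) and with the acinar covariate (2.8e-14). It called the list downward among Q- and R-tagged animals (1.25e-07) and with quality weights (0.0215).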

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

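The tests of the insulin ratio by inserts and by acinar cells, the bounds for the counts over other splits, the simulated shares, the shares with a control kept out of the calls, the shares by direction and the label check of controls 1 to 3 were chosen after the results were seen; the tests of the genes called without Traf6 KO 3 and of the label of control 4 were set before. Among the 4 controls, 132 values were searched for a library far from the other 3 by Dixon's criterion, which chance meets in about 1 in 20 groups, and 8 were found. Of these, 5 belonged to the library labelled control 4, 2 to control 1 and 1 to control 2. Many of these values are not independent, since several are markers of one cell type.

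Control 1 had an acinar-list share of counts of 20.3% against 0.467% to 3.24% in the other controls, and its Prss2 level was 10350 CPM against 186.5 to 1119 CPM. The Fis1 level of control 2, 58.8 CPM, lay below the 65.9 to 67.1 CPM of the other controls. The library labelled control 4 had a macrophage and myeloid mean of 4.94 against 3.46 to 3.62, Tyrobp at 16.7 CPM against 3.82 to 4.41 CPM, C1qb at 76.6 CPM against 21.7 to 23.8 CPM and Adgre1 at 12.1 CPM against 2.93 to 4.07 CPM. Its Ins1 to Ins2 ratio was 0.175 against 0.336 to 0.358.

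The number of genes called was 0 in all 7 libraries but 701 without Traf6 KO 3, and acinar cells carried into the preparations would set control 1, the control richest in acinar counts, on the Traf6 KO side in these genes. It lay on that side of the mean of controls 2 to 4 in 86.6% of the 689 genes also tested in all libraries (90.1% of higher and 72.2% of lower genes), against 46.2% to 51.3% in simulated data where it does not change. With genes called in Traf6 KO 1 and 2 against a pair of controls 2 to 4, and compared with the remaining control, the share was 85.2% to 95.2%, in line with acinar carry-over as a source of many of these calls (86.8% to 95.1% of higher and 75.2% to 97.7% of lower genes). Loss of Traf6 would set Traf6 KO 3 on that side as well, and it lay there in 72.6%, between the bounds set for and against this explanation (69.8% of higher genes and 84.2% of lower genes, where simulated data with Traf6 KO 3 unchanged gave 51.9% to 58.5% in all, 49.7% to 57.5% and 50.0% to 65.7%). With a control kept out of the calls its share was 71.1% (control 2), 70.3% (control 3) and 47.7% (the library labelled control 4, with an acinar share of 3.24% against 1.64% in Traf6 KO 3), with 48.9% to 75.0% of higher and 36.4% to 47.7% of lower genes, which for the lower genes goes against the 84.2%, and a part from Traf6 loss stays open and cannot be told apart from acinar content.

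Ins1 stood below its usual proportion to Ins2 in the 3 Traf6 KO libraries and in the library labelled control 4. Acinar carry-over is argued against, since the log2 ratio ranged over only 0.07 across the Traf6 KO libraries while their acinar share ran from 1.64% to 56.4%. A wrong label of the library labelled control 4 stays open, and its Traf6 level was the lowest of the 7. Among 455 genes with p under 0.01 and no overlap between Traf6 KO and controls 1 to 3, it lay nearer the Traf6 KO mean in 22.2%. The same check gave 27.5% for control 1, 7.0% for control 2 and 8.9% for control 3. It cannot decide, since no Traf6 KO library was put through it. The Traf6 KO mean also includes acinar shares of 56.4% and 43.1%, against 3.24% in the library labelled control 4, and acinar-rich control 1 scored highest. A candidate explanation is that one copy of Ins1 is replaced by an insert, as in some Cre driver alleles, in the Traf6 KO mice and in the library labelled control 4 but not in controls 1 to 3: the median ratio of Traf6 KO was 0.491 times that of control. That value was seen before the explanation was made, and the labels name no driver, so it cannot be told apart from an effect of Traf6 loss, which the library labelled control 4 alone does not exclude.

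The number of genes called says nothing about chance, since the real split called 0 genes, which all 35 of 35 splits of the 7 libraries reach, with 564 in the highest other split. At an unadjusted p under 0.05 the real split had 2589 genes, and 2 of the 35 splits had as many, the real one and one with 3198, so chance is not excluded for this count. The split with 564 and 3198 genes sets control 1, Traf6 KO 1 and Traf6 KO 2, the 3 libraries with the largest acinar shares, against the rest, which points to a structure of the samples. For gene lists called by camera at the preset correlation, the real split called 13, and 20 of the 35 splits called as many, with 19 in the highest other split and 7 in the lowest, so chance is not excluded for the number of lists either.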

How the results depend on the processing

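The 4 alternatives chosen after seeing the data are those that leave out Traf6 KO 3 together with an acinar covariate, leave out the 3 acinar-rich libraries, drop acinar list genes, or use plain library totals for cell-type markers; the others were planned. Where no cause is named, the cause was not tested. The count of 0 changed genes by edgeR stayed at 0 under DESeq2 size factors, upper-quartile factors, limma-voom, no low-count filter, a mean CPM of at least 1, the tag series as a term, Q- and R-tagged animals alone, the myeloid covariate, the acinar covariate with Traf6 KO 3 left out, and without acinar list genes. The DESeq2 Wald test called 634 genes (438 higher, 196 lower) and limma-voom with quality weights 1046 (669 higher, 377 lower). The acinar covariate gave 3 genes (3 higher, 0 lower), and leaving out the 3 acinar-rich libraries, which leaves 1 Traf6 KO library assumed to vary like the controls, gave 67 (61 higher, 6 lower). Leaving out each library in turn gave 0 to 701 genes (0 to 568 higher, 0 to 133 lower), where every value above 0 came without Traf6 KO 3. Where edgeR called 0 genes, its smallest adjusted p ranged from 0.0512 among Q- and R-tagged animals to 0.651 with the acinar covariate and Traf6 KO 3 left out. Scaling moved the median of all genes from 0.005 to 0.027 with DESeq2 size factors and -0.03 with upper-quartile factors.

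The number of lists called by camera, 13 of 29, was 10 to 13 under the other scalings, filters, covariates and tag settings, 8 with the acinar covariate and Traf6 KO 3 left out, 0 with an estimated correlation, 0 by fry and 4 by fry in either direction, and 8 (without control 2) to 13 when each library was left out. The unfolded protein response and the disallowed and dedifferentiation genes were called in the same direction in 20 of 20 camera alternatives at the preset correlation, beta-cell identity in 19, nuclear oxidative phosphorylation in 18, the cell cycle in 15, stellate markers and ribosomal proteins in 14, lymphocyte markers, Toll-like and interleukin-1 receptor components and apoptosis in 12, and endothelial markers and the interferon response in 9. Acinar markers were called upward in 16 of 19, and the acinar covariate set their median near 0 by construction. The log2 fold change of Traf6 stayed below 0 in all alternatives except the acinar covariate with Traf6 KO 3 left out (0.091), a fit of few libraries with the covariate close to the genotype, and it was -0.55 to -0.24 when each library was left out. The acinar difference was 2.17 to 5.27 when each library was left out, 2.80 on plain library totals and 1.05 as a mean z-score. The difference in log2 Ins1 to Ins2 was -1.04 to -0.70 when each library was left out.

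Whether the replicate numbers pair the libraries could not be told. The correlations of same-numbered libraries' deviations from their group means were 0.596, -0.177 and 0.454. Such correlations also followed acinar content: acinar-rich control 1 gave 0.596, 0.533 and -0.736 with Traf6 KO 1, 2 and 3. With the number as a replicate block, edgeR called 6 genes (6 higher, 0 lower) and camera 16 lists. The library labelled control 4 has no Traf6 KO library of the same number. It is alone in its block and adds nothing to the genotype difference in that fit.

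Of 99 named genes, 68 kept their sign in all alternatives and 51 passed in at least 1, mostly with quality weights (43), the DESeq2 Wald test (36) or without Traf6 KO 3 (23). Among the 99, 29 higher and 22 lower genes had no overlap between groups, so leaving out a library could not turn their sign. Sign changes by setting, as log2 fold changes, were as follows. With the 3 acinar-rich libraries left out, the sign changed for Pdx1 (0.092), Mafa (0.34), Slc2a2 (0.013), Gcg (0.35), Pink1 (-0.32), Fundc1 (-0.15), Optn (0.16), Il1r1 (0.12), Bhlha15 (-0.15) and Rpl23 (-0.24). With quality weights it changed for Slc2a2 (0.029), Bnip3 (0.021), Bnip3l (0.036), Sqstm1 (-0.025), Tlr4 (0.19), Il1b (-0.61), Nfkbia (-0.71), Ddit3 (-0.50) and Egr2 (-0.63). The acinar covariate changed it for Slc2a2 (0.042), Pink1 (-0.21), Fundc1 (-0.061), Il1r1 (0.11), Prss2 (-0.02) and Rpl23 (-0.066). The acinar covariate with Traf6 KO 3 left out changed it for Slc2a2 (0.038), Sqstm1 (-0.041), Tlr4 (0.175), Il1r1 (0.048), Il1b (-1.20), Nfkbia (-0.17), Mki67 (-0.092), Spock3 (-0.004), Reg2 (-0.30), Fn1 (-0.11), Dcn (-0.335), Ifit3 (0.515). Among Q- and R-tagged animals it changed for Bnip3l (0.061), Sqstm1 (-0.023), Clec16a (-0.061), Myd88 (0.063), Tlr4 (0.33), Il1b (-1.36), Nfkbia (-0.82), Tnfaip3 (-0.43), Ddit3 (-0.70), Adgre1 (0.24) and Egr2 (-0.20). Bnip3l changed with DESeq2 size factors (0.014), the DESeq2 Wald test (0.006), the tag series as a term (0.001) and without acinar list genes (0.011). Nfkbia changed with the tag series as a term (-0.15) and limma-voom (-0.024), and Tlr4 with the myeloid covariate (0.082). The replicate block changed Myd88 (0.002), Tlr4 (0.27), Nfkbia (-0.13) and Adgre1 (0.011). When each library was left out, ranges that span 0 were those of Slc2a2 (-0.093 to 0.08), Gcg (-0.302 to 0.054), Bnip3 (-0.131 to 0.03), Bnip3l (-0.062 to 0.081), Clec16a (-0.012 to 0.198), Myd88 (-0.148 to 0.029), Tlr4 (-0.84 to 0.24), Il1r1 (-0.32 to 0.11), Il1b (-1.49 to 2.12), Nfkbia (-0.745 to 0.59), Tnfaip3 (-0.295 to 2.67), Ddit3 (-0.58 to 1.08), Adgre1 (-1.03 to 0.082), Egr2 (-0.14 to 3.98) and Egr3 (-0.17 to 4.27).

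Depth was similar across libraries, but acinar transcripts took up to 56.4% of counts, so that fewer counts were left for islet genes: Traf6 had 163 counts in Traf6 KO 1 and 915 in control 2.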

Other observations

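The test of the neighbours of Traf6 was chosen after the result was seen, and the genes outside the rule for named genes (Xist, Ddx3y, Fos, Jun and Commd9) were chosen after their values were seen. Traf6 KO 3 differed from the other 6 libraries in several ways that the labels do not describe. It held 12998 counts of Xist, the RNA of the inactive X chromosome, and 0 counts of the Y-linked genes in the list, where the other libraries held 0 to 11 counts of Xist and 1221 to 4252 counts of Y-linked genes. Ddx3y, which is Y-linked, stood at 34.4 to 51.1 CPM in those 6 libraries. These counts mark Traf6 KO 3 as from a female and the others as from males, although the labels name no sex. This library thus differed in sex from every control, and a sex difference cannot be told apart from its other differences. The summed level of immediate-early and heat-shock genes was 31758 CPM in Traf6 KO 3, 2683 and 2651 CPM in Traf6 KO 1 and 2, and 3775, 10420, 9538 and 3369 CPM in the libraries labelled control 1 to 4. Fos stood at 2658 CPM in Traf6 KO 3 against 95.4 to 869.0 CPM in the others, and Jun at 3990 CPM against 67.8 to 1619 CPM. The summed level of lymphocyte markers was 800.7 CPM in this library against 30.2 to 185.6 CPM in the others.

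In a principal component analysis of the 7 libraries, the first component held 59.3% of the variance and placed Traf6 KO 1 (-67.6), Traf6 KO 2 (-43) and control 1 (-16.8) on one side and the other 4 libraries between 21.9 and 35.7 on the other. The second held 15.5% and placed Traf6 KO 3 at 42.9, Traf6 KO 1 and 2 at 8.2 and 4.2, and the 4 libraries labelled control between -21.6 and -5.1.

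Commd9, which lies 185 kb from Traf6 on chromosome 2 (101886247 to 101901646 on GRCm38), stood at 29.5 ± 2.15 CPM in control (SD, n = 4) and 19.8 ± 0.776 CPM in Traf6 KO (SD, n = 3), lower in each of the 3 Traf6 KO libraries than in any control, and did not pass (log2 fold change -0.57 ± 0.098, edgeR adjusted p = 0.1765). Sequence around the engineered allele could differ between the groups and move neighbouring genes. Among 38 tested genes within 5 Mb of Traf6, 8 (21.1%) had an unadjusted p under 0.05, against 16% of other genes (Fisher's exact p = 0.376), which is too few genes to tell.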
